A study of Rattus norvegicus with 16 samples.

How the data were processed

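Total RNA from the hearts of 16 rat pups was labelled with Cy3, 100 ng per animal per the labels' protocols, and hybridised to Agilent rat miRNA arrays, 1 array per animal. The groups were HHR females, HHR males, NHR females and NHR males, 4 animals each, taken from the labels. Replicates are separate animals per the design text. The authors deposited the scanner output of each array. Per the file headers, the intensity of each spot was read by Agilent Feature Extraction 10.7.3.1, with spatial detrending and background subtraction and no scaling between arrays, and the processed, median, background and total gene signals are intensities on a linear scale. Each array held 13540 spots for 677 rat miRNAs, 20 spots per miRNA in 1 to 4 probes. The file headers name the rn4 build. The authors also deposited a table of log2 values, 1 per miRNA and array; the submitters' processing notes name limma. Set against the scanner files, its columns correlated at r = 0.999 with the log2 median signal of the same array, with column medians from 6.13 to 6.15. Its background correction, offset, scaling and centring are not given in the sources used here, and it served as an alternative only. Across the 116 dimmer tested miRNAs its mean values rose by 0.137 per log2 unit of the level computed here, and across the 117 brighter ones by 0.690, so differences in it are smaller. The detection flags (other values, 0 or 1) are those the authors deposited in the scanner output.

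Levels were computed from the processed signal. Spots marked as outliers by the scanner software and control spots were left out, spots of a probe were averaged (all of them where every spot was an outlier), and each array was scaled so that the 75th percentile over the 258 probes well above background on all 16 arrays was equal. A probe counted as well above background where most of its spots carried that flag. The probes of a miRNA were averaged on the linear scale, values were raised to a common floor of 1.92 (0.94 on the log2 scale, the median over arrays of the lowest level of a detected miRNA), and log2 was taken. miRNAs detected on at least 4 arrays were tested, 233 in all, and 186 of the 677 were detected on every array. Fold changes of dim miRNAs depend on the floor. A miRNA detected on no array of 1 strain is given as a bound against the lowest level of a detected miRNA on each of that strain's arrays. All arrays of the other strain enter the bound, also those where the miRNA was not detected.

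limma 3.58.1 in R 4.3.3 was used to fit 1 mean per group to all 16 arrays, with moderated variances, and 5 contrasts were tested: strain over both sexes, strain in females, strain in males, sex over both strains, and the interaction. p values were adjusted by the Benjamini-Hochberg method over the 233 miRNAs with a threshold of 0.05. Lists of miRNAs (families, genomic clusters, miRNAs reported in hypertrophy and markers of other cell types, 21 lists of which 16 had at least 3 tested members) were tested for the strain contrast with camera and a correlation estimated from the residuals. Preset correlation 0.01 and fry, which asks whether a list moves on balance one way without comparing it with other miRNAs, were alternatives. Of the 151 names in the lists, 6 were not on the array. Array summaries were compared with two-sided exact permutation tests over all 12870 splits. The lists, the tests and the rule for named miRNAs were fixed before the data were examined. The rule took, among miRNAs past the threshold with the same sign in both sexes, the 12 largest differences each way, with bounds named separately (up to 5 each way), up to 4 called members of each list or else the 2 with the smallest p, up to 5 each way (or the 3 smallest p) for each other comparison, and miR-1, miR-133a, miR-208a and miR-208b always. Within each sex, called miRNAs detected on no array of at least 1 of the groups compared (4 in females and 4 in males) were left out of this ranking, which was decided after the data were seen.

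Alternatives covered the signal column, a normexp background (offset 50), quantile normalization, a percentile over all probes, no scaling, the mean of log2 probe values, the filter on dim miRNAs, a floor 4 times higher or lower, moderation with trend and robust settings, array weights, the authors' table, slide and replicate number as blocks, fits without a sex term or with the arrays of 1 sex, and leaving out each array. The mean signal of each spot was not used here, so normexp was run on the median signal and the median local background. Its offset was added before the arrays were scaled, so it came out lower on brighter arrays. Array brightness as a covariate, median centring, scaling to the 2 hybridisation spike-in controls with signal and a restriction to bright arrays were added after seeing the data. The 6 scalings compared are the reported one, quantile normalization, the percentile over all probes, no scaling, median centring and spike-in scaling. The arrays lay on 2 slides, each scanned once, with 2 arrays of each group on each slide, so slide and strain were balanced. Precursor positions were matched by name to the GRCr8 gene table, used only for neighbours and overlapping genes, and 230 of the 233 tested miRNAs matched.

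The fit was tested on simulated data with the real means and the moderated spreads of the 233 miRNAs, drawn independently, 45 of them changed in random directions, over 20 runs. For the strain contrast over both sexes it recovered 57.7% of differences of 0.2, 85.7% of 0.4 and 97.0% of 0.8 on the log2 scale, with 4.63% of calls false. In females the shares were 43.0%, 74.0% and 94.7%, and in males 44.7%, 75.0% and 92.7%. The simulated data held no differences in array brightness, no scaling step and no floor. Neither the recovery nor the share of false calls therefore covers errors from these.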

Results

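Hearts of 16 rat pups were profiled on day 2 after birth, 8 from HHR (the Hypertrophic Heart Rat, a strain with polygenic cardiac enlargement) and 8 from NHR (the Normal Heart Rat, its normal-sized counterpart). Each strain gave 4 females and 4 males, with 1 one-colour array per animal and no pooling. The labels differ on the tissue, naming the whole heart in one place and ventricles cut away from the atria in another. Each array carried probes for 677 rat miRNAs. Between 200 and 239 miRNAs were detected per array, 186 were detected on all 16 arrays and 417 on none. The brightest miRNAs took a similar part of the signal in both strains, the 10 brightest holding 44.8% ± 0.606 in HHR and 45.2% ± 0.646 in NHR (SD, n = 8 each; two-sided exact permutation test, p = 0.198, Benjamini-Hochberg adjusted p = 0.297 over 3 summaries). HHR arrays were brighter before scaling, with a 75th percentile of signal of 469.6 ± 37.3 against 378.4 ± 87.3 in NHR (SD, n = 8 each; two-sided exact permutation test, p = 0.0191, adjusted p = 0.0573). The NHR arrays themselves lay apart, 3 of them between 442.7 and 502.9 and 5 between 294.7 and 326.8. The brightness difference, 91.2, was 106.4 within slide 1 and 76.0 within slide 2 (4 arrays against 4 each, two-sided exact permutation tests, p = 0.114 and 0.229). It passed the threshold without NHR female 3 (109.0) or NHR male 2 (108.2), with adjusted p from 0.0182 to 0.119 over the arrays left out in turn. The share of the 10 brightest passed without NHR female 3 (a difference of -0.630 percentage points, with adjusted p from 0.0315 to 0.572 over the arrays), and differed by -0.537 and -0.303 points within slides 1 and 2 (two-sided exact permutation tests, p = 0.171 and 0.514). No spot was saturated. The number of arrays limits the precision of every value.

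The main question was which miRNAs differ between the neonatal hearts of the 2 strains. The sizes of these hearts are not given in the sources used here. HHR hearts had lower levels of 6 miRNAs encoded side by side on chromosome X, and higher levels of miR-34a and miR-378. Of the X-linked neighbours, miR-500 was 1.64-fold lower in HHR (log2 difference -0.71 ± 0.033, SE, 8 arrays against 8, limma adjusted p = 1.32e-09), miR-532-3p was 1.62-fold lower (-0.70 ± 0.054, adjusted p = 1.79e-07) and miR-362 was 1.59-fold lower (-0.67 ± 0.069, adjusted p = 3.46e-06). miR-188 was 1.82-fold lower (-0.86 ± 0.16, adjusted p = 8.49e-04). For miR-500, miR-532-3p and miR-362, all 8 HHR arrays lay below all 8 NHR arrays. In the GRCr8 assembly the precursors of these miRNAs each lie within 10 kb of the next and inside the chloride channel gene Clcn5. The remaining products of this locus, miR-532-5p (-0.59 ± 0.029) and miR-362* (-0.57 ± 0.033), were named after their values were seen, and both were lower (adjusted p = 1.32e-09 and 6.24e-09). The median of the 6, -0.68, stayed negative under all 6 scalings, with 3 of the 6 called without scaling and with spike-in scaling, and it was -0.079 with 0 called in the authors' value table. That table compresses levels. Strain differences in it had a slope of 0.162 on those reported here among the 116 dimmer tested miRNAs, miR-188, miR-362 and miR-532-3p among them. The slope was 0.532 among the 117 brighter ones, which include miR-500, miR-532-5p and miR-362*, also not called there. Whether the compression accounts for the lost calls was not tested.

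Among miRNAs higher in HHR, miR-34a, a miRNA induced by p53, differed most, by 1.94-fold (log2 difference 0.96 ± 0.048, SE, 8 arrays against 8, adjusted p = 1.52e-09). Both arms of the miR-378 hairpin, which lies within the PGC-1β gene Ppargc1b, were higher, miR-378 by 1.33-fold (0.41 ± 0.034, adjusted p = 3.26e-07) and miR-378* by 1.30-fold (0.37 ± 0.037, adjusted p = 1.91e-06). miR-218, whose precursors lie within Slit2 and Slit3, was 1.30-fold higher (0.38 ± 0.040, adjusted p = 4.37e-06). On all 8 HHR arrays these 4 miRNAs, with miR-338 (0.57 ± 0.10) and miR-598-3p (0.37 ± 0.049), lay above all 8 NHR arrays. The other members of the 12 largest higher differences were miR-31 (0.69 ± 0.26), miR-410 (0.40 ± 0.082), miR-341 (0.36 ± 0.11), miR-431 (0.33 ± 0.085), miR-675* (0.22 ± 0.046) and miR-490* (0.22 ± 0.039), with adjusted p from 5.59e-04 to 0.0417. The direction of 8 of these 12 miRNAs turned negative with a normexp background, miR-31, miR-338, miR-410, miR-218, miR-598-3p, miR-341, miR-431 and miR-675*. There miR-34a, miR-378, miR-378* and miR-490* stayed positive, and of these only miR-34a and miR-378 remained called. The normexp offset was added before scaling, so it came out lower on the brighter HHR arrays and pulled dim miRNAs down by construction. These reversals therefore do not show a dependence on the background itself. The miR-31 call was lost without HHR female 2 or 3, HHR male 2, 3 or 4, NHR female 4 or NHR male 2 or 4 (0.53 to 0.70).

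**Figure D1:**
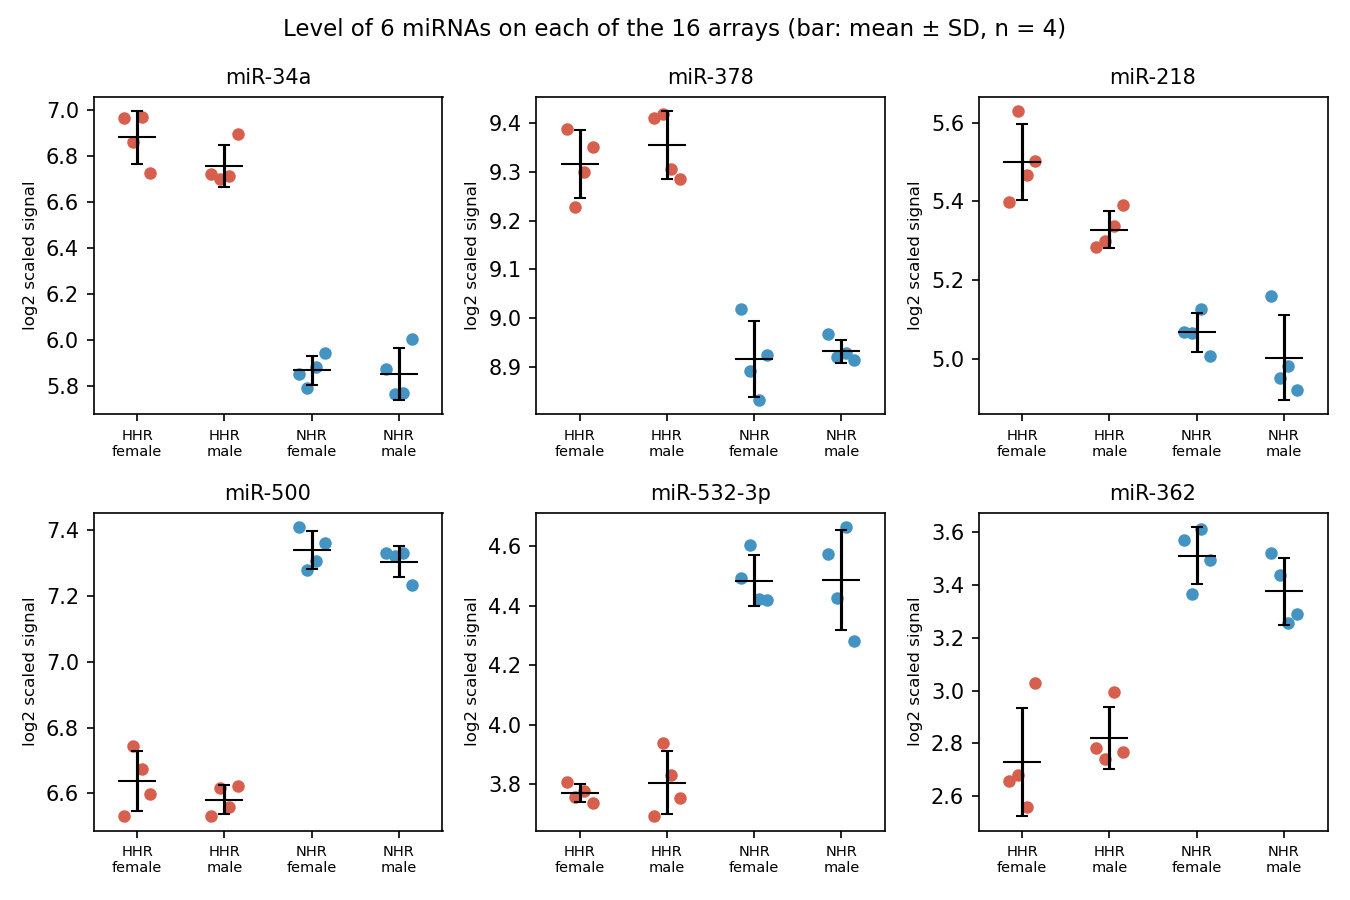
Log2 scaled signal (vertical axis) of 6 miRNAs on each array, by strain and sex; points are single arrays and bars are the mean ± SD of 4. For miR-34a, miR-378 and miR-218 every HHR array lies above every NHR array, and for miR-500, miR-532-3p and miR-362 every HHR array lies below.

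The largest fitted decreases in HHR belonged to dim miRNAs with wide spread. These were miR-3584-5p (-2.84 ± 0.79, detected on 2 HHR and 6 NHR arrays), miR-466b (-2.13 ± 0.33, 2 and 8), miR-3588 (-2.06 ± 0.39, 2 and 6) and miR-32* (-1.89 ± 0.38, 1 and 5), with adjusted p from 1.88e-04 to 0.00969, and their sizes rest on values near the detection floor. miR-328a* was detected on 4 NHR arrays and no HHR array, with a computed bound of 2.90-fold higher in NHR (limma adjusted p = 1.59e-04). The bound averages all 8 NHR arrays, also those without detection, so it is not a strict lower limit. The miR-328a* call was lost under 3 of 17 alternatives, over which the difference shrank to as little as -0.085. Detected on more HHR arrays were miR-192, known from liver and kidney (1.76-fold lower, -0.82 ± 0.067, adjusted p = 3.45e-07, detected on 6 HHR and 8 NHR arrays), miR-211* (-0.95 ± 0.16, adjusted p = 2.85e-04, 5 and 8) and miR-672 (-0.83 ± 0.17, adjusted p = 0.00132, 8 and 8). These 3 calls were lost in the authors' value table, and that of miR-672 also without scaling and with spike-in scaling. The table compresses dim miRNAs, but whether this accounts for the calls lost in it was not tested. let-7d* (-0.69 ± 0.17, adjusted p = 0.00526) lay near the floor on all arrays. Its call was lost under 7 of 17 alternatives, and with a floor 4 times higher all its values lay at the floor and no difference was left.

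**Figure D2:**
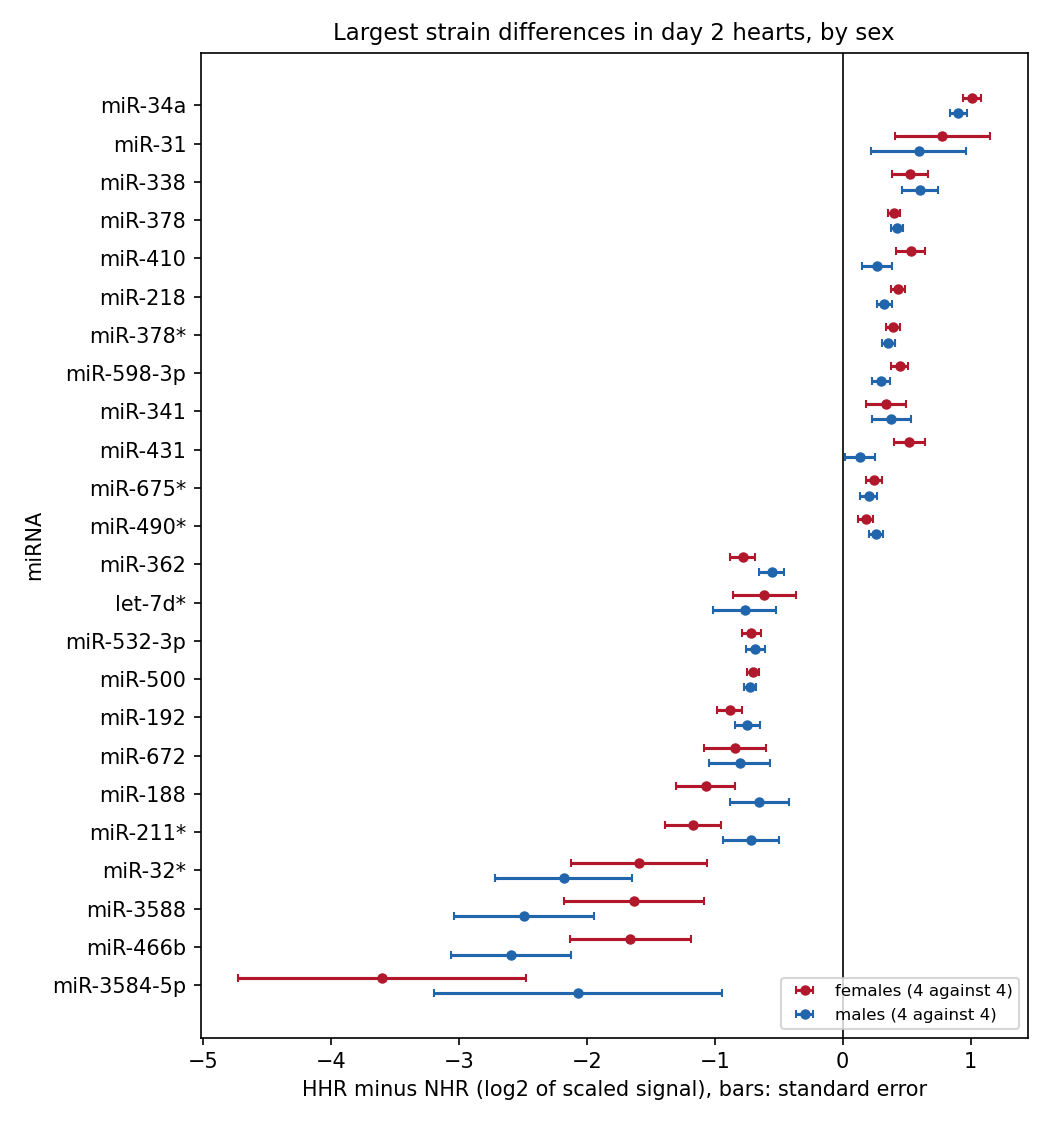
HHR minus NHR on the log2 scale (horizontal axis) for the 24 miRNAs with the largest called differences (vertical axis), fitted separately in females and males; bars are standard errors. The miRNAs were chosen among those with the same sign in both sexes, and range from miR-34a (1.01 in females and 0.90 in males) to miR-3584-5p (-3.60 and -2.07).

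In all, 127 of 233 tested miRNAs differed between the strains, 21 higher and 106 lower in HHR, of which 2 higher and 15 lower differed by at least 1.5-fold. In 33 of them the values of the strains did not overlap, against 0.0155% of miRNAs by chance. The direction of small differences depended on how the arrays were scaled. By construction 4 of the 5 other scalings moved nearly all differences alike, by a median of 0.17 to 0.34 log2 with 97.0% to 100% of miRNAs within 0.1 of it, so that most negative differences smaller than this shift turned positive. The median of all tested miRNAs was shifted by -0.106 log2, and the share of lower calls, 83.5% here, was 51.4% of 70 calls with the scanner's total gene signal, 44.1% of 102 with quantile normalization, 13.5% of 155 with a percentile over all probes, 20.8% of 48 without scaling, 31.0% of 87 with median centring, 40% of 25 with spike-in scaling, 98.8% of 164 with a normexp background and 13.3% of 15 in the authors' value table. Of the 72 calls with a difference under 0.32 log2, 61 changed sign under at least 1 of the 6 scalings, against 2 of the 55 larger ones. A core of 22 miRNAs, 12 higher and 10 lower, passed the test under all 6 scalings. The 5 other scalings moved most differences upward, so the sign of the 12 higher ones was hardly put to the test. The core held, among others, miR-34a, miR-378, miR-378*, miR-218, miR-338, miR-598-3p, miR-31, miR-410, miR-431, miR-500, miR-532-3p, miR-188, miR-192 and miR-211*. Its lower members also included miR-3584-5p, miR-466b, miR-3588, miR-32* and miR-328a*, whose values lie near the floor. With a normexp background miR-218, miR-338, miR-598-3p, miR-31, miR-410 and miR-431 turned negative. With array brightness as a covariate 74 miRNAs were called, and among arrays with a 75th percentile above 400 (8 HHR and 3 NHR) 61. With slide as a block 128 were called. Within the 2 slides, each holding 2 arrays of every group, 37 and 47 were called. Of the 37 called on slide 1, 35 had the same sign on slide 2, and of the 47 called on slide 2, 46 had it on slide 1, as did 203 of all 233 tested.

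**Figure D3:**
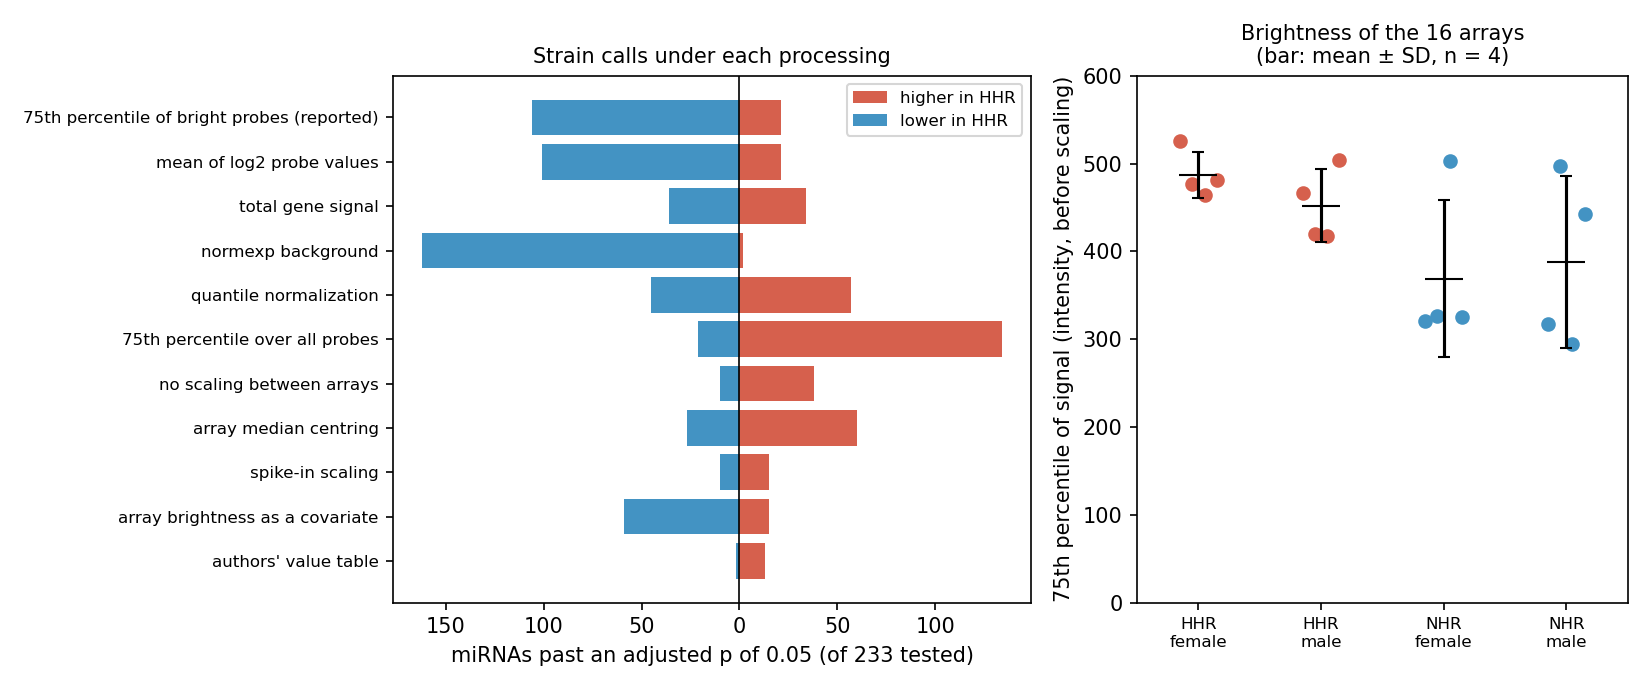
Left, number of miRNAs (horizontal axis) higher or lower in HHR at an adjusted p under 0.05, of 233 tested, under each processing (vertical axis); the reported one gave 21 higher and 106 lower, and the percentile over all probes 134 higher and 21 lower. Right, the 75th percentile of unscaled signal (intensity) of each array by group, with the mean ± SD of 4; 5 of the 8 NHR arrays lie below 327.

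Among cardiac and skeletal myomiRs, the abundant miR-1 (log2 difference -0.10 ± 0.041, SE, adjusted p = 0.0526) and miR-133a (-0.059 ± 0.027, adjusted p = 0.0788) did not pass the threshold. miR-1 did without HHR female 4, HHR male 3 or NHR female 3 (-0.13 to -0.11), and miR-133a did without HHR female 4 or NHR male 2 (-0.072 to -0.070). Both turned positive under all 5 other scalings and passed as higher with a percentile over all probes (0.18 and 0.22), and with array weights both passed as lower (-0.12 and -0.064). miR-1 also passed as lower under 3 other settings. miR-208, the miR-208a of the Myh6 intron, and miR-208b-5p were detected on no array. The other arm of the miR-208a hairpin, miR-208*, named after its values were seen, was detected on all 16 and called lower (-0.13 ± 0.052, adjusted p = 0.0433), but turned positive under all 5 other scalings. It passed as higher with quantile normalization (0.13) and with a percentile over all probes (0.15). Its call as lower was lost without HHR female 1, 2 or 3, HHR male 1 or 2, NHR female 3 or 4 or NHR male 1 or 3 (-0.14 to -0.11). In this list 3 of 6 tested members were lower, miR-499, encoded in the myosin gene Myh7b (-0.28 ± 0.027, adjusted p = 1.80e-06), miR-133b (-0.15 ± 0.031, adjusted p = 0.00132) and miR-208b-3p, from the β-myosin gene Myh7 (-0.17 ± 0.061, adjusted p = 0.0354). Adjusted over the list alone 4 were lower. The miR-499 difference exceeded the median shift, at -0.17 relative to it, and turned positive under 2 of the 5 other scalings. The directions of miR-133b and miR-208b-3p turned under 4 and 5 of them, and the miR-208b-3p call was lost without HHR female 1 or 2, HHR male 2 or 4, NHR female 1, 3 or 4 or NHR male 1, 2 or 4 (-0.16 to -0.14). Calls in this list were 3 higher and 0 lower with a percentile over all probes, and none without scaling, with median centring or with spike-in scaling. The list as a whole did not stand apart from other miRNAs (camera adjusted p = 0.564).

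Of miRNAs reported to promote hypertrophy, 1 of 9 tested was higher and 6 were lower (also 1 and 6 adjusted over the list alone; camera adjusted p = 0.726). Besides miR-499, the lower ones included miR-195 (-0.34 ± 0.042, adjusted p = 2.30e-05), miR-21 (-0.13 ± 0.029) and miR-23a (-0.13 ± 0.025). The list's median, -0.13, turned positive under all 5 other scalings, and miR-21 and miR-23a were called higher with a percentile over all probes (0.15 for both). miR-195 stayed negative under each scaling but was called under only 3 of the 6. Over the alternatives its difference shrank to as little as -0.0031. The higher member was miR-199a-5p (0.20 ± 0.072, adjusted p = 0.0335), whose call was lost without HHR female 2 or 3, HHR male 3 or 4, NHR female 4 or NHR male 2 or 4 (0.17 to 0.19). Of miRNAs reported to oppose hypertrophy, 2 of 10 were higher, miR-34a and miR-378, and 2 lower, miR-133b and miR-26a (-0.087 ± 0.029; also 2 and 2 adjusted over the list alone; camera adjusted p = 0.564). This list's median (-0.050) and mean (0.084) differed in sign, and miR-26a turned positive under all 5 other scalings. With a percentile over all probes both lower members, miR-26a (0.19) and miR-133b (0.13), were called higher, as were miR-1 and miR-133a. In the miR-34 family, 1 of 3 members was higher, miR-34a (1 adjusted over the list alone; camera adjusted p = 0.564).

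The miR-15 family, linked to cell cycle arrest of neonatal cardiomyocytes, had 4 lower members of 5 (5 adjusted over the list alone; camera adjusted p = 0.564). miR-497 (-0.33 ± 0.032, adjusted p = 1.42e-06) and its neighbour miR-195 were well below the median shift, with miR-497 turning positive under 1 of the 5 other scalings. miR-16 (-0.11 ± 0.028) and miR-15b (-0.10 ± 0.029) lay at the median shift and turned under 4. Both were called higher with a percentile over all probes (0.17 and 0.18). Neither was called without scaling, with median centring or with spike-in scaling. The medians of the let-7, miR-30, miR-23/27/24 and miR-181 lists, all negative, turned positive under 4 of the 5 other scalings, and that of the miR-29 family under 5. With a percentile over all probes, the members of the first 4 of these lists that are given below with values were called higher, except miR-181d. None of those members was called without scaling, with median centring or with spike-in scaling. In the let-7 family 3 of 8 members were lower, let-7d (-0.13 ± 0.022), let-7i (-0.13 ± 0.026) and let-7a (-0.12 ± 0.027; 3 adjusted over the list alone; camera adjusted p = 0.726). In the miR-30 family 4 of 5 were lower, miR-30c (-0.15 ± 0.023), miR-30e (-0.13 ± 0.027), miR-30a (-0.12 ± 0.025) and miR-30d (-0.12 ± 0.033; 5 adjusted over the list alone; camera adjusted p = 0.564). All 5 members of the miR-23/27/24 clusters were lower (5 adjusted over the list alone; camera adjusted p = 0.564), with miR-23b at -0.14 ± 0.025, miR-24 at -0.13 ± 0.026 and miR-27a at -0.13 ± 0.029. All 4 members of the miR-181 family were lower (4 adjusted over the list alone; camera adjusted p = 0.564), from miR-181d (-0.21 ± 0.028) and miR-181c (-0.14 ± 0.026) to miR-181a (-0.14 ± 0.030) and miR-181b (-0.10 ± 0.031). In the miR-29 family, which targets collagens, 1 of 3 was lower, miR-29c (-0.15 ± 0.031; 1 adjusted over the list alone; camera adjusted p = 0.831). In the miR-17~92 cluster and its paralogs none of 10 passed the limma test, and none did adjusted over the list alone (camera adjusted p = 0.642). The smallest p values there belonged to miR-18a (0.075 ± 0.033, adjusted p = 0.0712) and miR-25 (-0.062 ± 0.028, adjusted p = 0.0755). miR-18a passed without HHR male 2 or NHR female 3 (0.087 to 0.091), and miR-25 without NHR male 4 (-0.076). The count of 0 depended on the scaling, since 10 members were called higher with a percentile over all probes, 7 with median centring, 3 with quantile normalization, 2 without scaling and 4 with the total gene signal, with 1 (miR-18a) higher with array weights and 1 (miR-25) lower with a normexp background.

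The Dlk1-Dio3 imprinted cluster had 5 of 20 tested members higher and 2 lower (3 and 1 adjusted over the list alone). miR-410, miR-341 and miR-431 were among the 12 largest higher differences, and miR-667 was lower (-0.33 ± 0.11, adjusted p = 0.0185), turning positive under 1 of the 5 other scalings. The call of another higher member, miR-379 (0.15 ± 0.062, adjusted p = 0.0481), was lost without HHR female 2 or 3, HHR male 3 or 4, NHR female 1, 2, 3 or 4 or NHR male 2 or 3 (0.12 to 0.16). The list passed camera with a preset correlation of 0.01 (adjusted p = 0.00154) and did not pass with an estimated correlation (adjusted p = 0.564). Its median was 0.062, moved to 0.021 without HHR female 2, 0.036 without NHR male 2, 0.10 without HHR female 1 and 0.10 without NHR male 1, and was -0.19 with a normexp background. It stayed positive under all 5 other scalings, which move most differences upward and so hardly test its sign. The count of 5 higher and 2 lower went to 15 and 0 with a percentile over all probes, 14 and 0 with quantile normalization, 12 and 0 without scaling and with median centring, 2 and 0 with spike-in scaling and 0 and 9 with a normexp background. The adjusted p with an estimated correlation ran from 0.306 to 0.991 over the other settings. The median was 0.030 on slide 1 and 0.12 on slide 2.

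Lists of markers of other cell types were compared next, and none of those tested passed camera. Of 4 tested leukocyte miRNAs 3 were lower in HHR (3 adjusted over the list alone; camera adjusted p = 0.564), the lymphocyte-enriched miR-150 (1.45-fold lower, -0.53 ± 0.039, adjusted p = 1.05e-07), the myeloid miR-223 (-0.47 ± 0.10, adjusted p = 0.00152) and miR-146a (-0.30 ± 0.044, adjusted p = 1.17e-04). The list median stayed negative under all 5 other scalings, where of the 3 called members only miR-146a turned positive, under 1, and the member not called turned under all 5. The 3 calls went to 2 with median centring, 1 with a percentile over all probes and 0 without scaling, with spike-in scaling and in the authors' value table. None of 3 erythroid miRNAs passed the limma test, and none did adjusted over the list alone (camera adjusted p = 0.708), with miR-144 at 0.069 ± 0.11 and miR-144* at -0.12 ± 0.10, and the list's median (0.037) and mean (-0.0053) differed in sign. With single arrays left out that median ran up to 0.10 and turned negative without HHR male 1 or NHR male 2 (at the lowest -0.0066), miR-144 ran from 0.013 to 0.14 and miR-144* from -0.18 to -0.065. With a percentile over all probes 2 of the 3 were called higher, and with a normexp background miR-144* was called lower (-0.26). Of 5 endothelial miRNAs 1 was higher, miR-218, and 2 lower, miR-126 (-0.20 ± 0.026, adjusted p = 4.48e-05) and miR-126* (-0.23 ± 0.047, adjusted p = 0.00132; 1 and 2 adjusted over the list alone; camera adjusted p = 0.708). Both arms of miR-126 turned positive under 3 of the 5 other scalings. Of the 6 scalings, miR-126 was called lower under 2 and miR-126* under 1, while miR-221 was called higher under 5. The endothelial list's median (-0.030) and mean (0.024) differed in sign. Of 6 fibroblast and fibrosis miRNAs 1 was higher, miR-199a-5p, and 2 lower, miR-21 and miR-10a-5p (-0.37 ± 0.11, adjusted p = 0.0113; 1 and 2 adjusted over the list alone; camera adjusted p = 0.708). miR-21 turned positive under all 5 other scalings and was called higher with a percentile over all probes (0.15). The miR-10a-5p call held under the reported scaling only. With quantile normalization, a percentile over all probes, no scaling or median centring, miR-199a-5p, miR-199a-3p and miR-214 were all called higher. This list's median (0.031) and mean (-0.013) differed in sign. With single arrays left out that median ran from 0.0054 (without HHR female 2) to 0.052 (without NHR male 1). Both tested smooth muscle miRNAs, miR-143 (-0.12 ± 0.020) and miR-145 (-0.13 ± 0.030), were lower, also adjusted over the list alone, and turned positive under 4 and 5 of the other scalings. Both were called lower under the reported scaling only, and miR-143 was called higher with a percentile over all probes (0.16). The hypoxia-induced miR-210 was 1.34-fold lower (-0.42 ± 0.062, adjusted p = 1.28e-04) and stayed negative under every scaling. Its difference shrank to as little as -0.079 over the 6 scalings, and it was called under 3 of them. Of 2 tested neural miRNAs 1 was lower, miR-7a (-0.29 ± 0.080, adjusted p = 0.00969, turning positive under 1 of the other scalings). Of the liver and endocrine list miR-192 was the 1 member tested. These last 4 groups had fewer than 3 tested members and no list test. None of the 10 epithelial miRNAs was detected on any array.

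The strain difference was then asked within each sex. In females 105 of 233 miRNAs differed, 15 higher and 90 lower in HHR, the higher led by miR-34a (log2 difference 1.01 ± 0.068, SE, 4 arrays against 4, limma adjusted p = 1.01e-07), miR-410 (0.53 ± 0.12), miR-338 (0.53 ± 0.14), miR-431 (0.52 ± 0.12) and miR-598-3p (0.44 ± 0.070). Among the lower, the largest fitted differences of miRNAs detected in both female groups were those of miR-3584-5p (-3.60 ± 1.12), miR-466b (-1.66 ± 0.47), miR-3588 (-1.63 ± 0.55), miR-32* (-1.59 ± 0.53) and miR-211* (-1.17 ± 0.22). The lower calls in females also include miR-3584-3p, which was detected on no female array. In males 48 differed, 9 higher and 39 lower, the higher led by miR-34a (0.90 ± 0.068, adjusted p = 2.86e-07), miR-338 (0.61 ± 0.14), miR-378 (0.42 ± 0.047), miR-378* (0.36 ± 0.052) and miR-218 (0.33 ± 0.057). Among the lower, miR-466b, miR-3588, miR-32* and miR-328a* were called in males (adjusted p from 0.00125 to 0.0125) but detected on no HHR male array, so the size of their differences is not given. Of those detected in both male groups, the largest were miR-672 (-0.81 ± 0.24), let-7d* (-0.76 ± 0.25), miR-192 (-0.75 ± 0.10), miR-500 (-0.72 ± 0.047) and miR-211* (-0.72 ± 0.22). Both sexes called 45 miRNAs, all in the same direction, 36 lower and 9 higher, where independent lists would share 15.1 and 0.579. The contrasts of the sexes share a pooled spread and the same scaling, so the excess cannot be read as replication alone. Across the 233 miRNAs, which are not independent replicates, the differences in the sexes correlated (Pearson r = 0.868, Spearman rho = 0.828), and 203 of the 233 had the same sign in both. The count in females fell to 69 without NHR female 4, and that in males to 24 when only the 8 male arrays were fitted. The split within each sex moved with the scaling as it did over both sexes, to 108 higher and 19 lower in females and 69 and 12 in males with a percentile over all probes. With slide as a block 105 and 49 were called, and within the 2 slides 24 and 32 in females and 9 and 16 in males.

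No miRNA differed in its strain effect between the sexes (limma, 0 of 233, 9 at an unadjusted p under 0.05, smallest adjusted p = 0.929). The smallest p values belonged to miR-423* (difference of differences -0.40 ± 0.13, SE), miR-30e* (-0.17 ± 0.061) and miR-15b (-0.15 ± 0.058). The larger count in females than in males is therefore not shown to be a difference between the sexes.

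Females and males were compared over both strains. No miRNA passed the threshold (limma, 0 of 233, 23 at an unadjusted p under 0.05). The closest were miR-421* from chromosome X (0.23 ± 0.047 log2, SE, 8 females minus 8 males, adjusted p = 0.0501) and the Dlk1-Dio3 members miR-379 (0.28 ± 0.062, adjusted p = 0.0514) and miR-136 (0.26 ± 0.062, adjusted p = 0.0736), with positive differences that missed the threshold. The result lay at the edge of the threshold, since 3 miRNAs passed when only those detected on all 16 arrays were tested, 10 without NHR male 1, 3 without HHR male 3, 2 without HHR male 4, 1 each without NHR female 1 and without NHR male 4, and 1, miR-421*, with the replicate number as a block, which is also the slide and row of the array. With slide as a block, and within each slide, 0 miRNAs passed for sex or for the interaction.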

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

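Within groups of 4, an array was singled out when its gap to the nearest of the others took a share of the group's range beyond Dixon's critical value. Of 299 groups examined over the named miRNAs and the array summaries, 21 held such an array, where chance gives about 14.95. In brightness, NHR female 3 stood apart, with a 75th percentile of signal of 502.9 against 320.4 to 326.8 on the other NHR female arrays. On the log2 scale, miR-34a was at 6.89 in HHR male 4 (others 6.70 to 6.72), miR-31 was at 1.96 in NHR female 4 (others 3.05 to 3.13), miR-598-3p was at 2.52 in NHR female 2 (others 2.69 to 2.70) and miR-3584-5p was at 3.45 in HHR female 3 (others 1.81 to 2.07). In the same way, miR-188 was at 2.45 in HHR female 1 (others 3.17 to 3.25), miR-672 was at 4.96 in NHR male 2 (others 3.97 to 4.11), miR-500 was at 7.23 in NHR male 4 (others 7.32 to 7.33) and miR-362 was at 2.99 in HHR male 3 (others 2.74 to 2.78). Further, let-7a was at 11.28 in NHR female 3 (others 11.38 to 11.39), miR-195 was at 5.32 in HHR male 1 (others 5.45 to 5.46), miR-16 was at 10.77 in NHR female 3 (others 10.68 to 10.699) and miR-15b was at 9.64 in HHR male 4 (others 9.71 to 9.72). Among the abundant families, miR-25 was at 7.94 in HHR female 4 (others 7.87 to 7.88), miR-30e was at 9.30 in NHR male 3 (others 9.37 to 9.38), miR-181a was at 7.87 in HHR female 3 (others 7.78 to 7.79) and miR-21 was at 11.23 in NHR female 2 (others 11.36 to 11.39). Last, miR-126 was at 9.90 in HHR male 2 (others 10.03 to 10.05), miR-7a was at 3.00 in HHR male 3 (others 2.67 to 2.72), miR-421* was at 3.66 in NHR female 1 (others 3.77 to 3.79) and miR-421* was at 3.36 in NHR male 4 (others 3.61 to 3.62). No miRNA was singled out by a difference between the sexes in its strain effect, since none passed the interaction test. No explanation was tested for these single arrays.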

How the results depend on the processing

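Brightness as a covariate, median centring, spike-in scaling and the restriction to bright arrays were chosen after the data were seen. The count of strain differences, 127, stayed within 1.5 times under 14 of 20 alternatives and moved to 70 with the total gene signal, 48 without scaling and 15 in the authors' value table, and to 74 with brightness as a covariate, 25 with spike-in scaling and 61 on bright arrays. In females 105 moved to 50 with the total gene signal, 42 with normexp, 64 with quantile normalization, 21 without scaling, 6 in the authors' table, 61 with brightness, 67 with median centring and 2 with spike-in scaling. In males 48 moved to 23 with the total gene signal, 7 with normexp, 81 with a percentile over all probes, 5 without scaling, 2 in the authors' table, 4 with spike-in scaling and 24 with only the 8 male arrays, which leaves fewer samples for the spread. The count for sex, 0, moved to 3 when only miRNAs detected on all 16 arrays were tested, where fewer tests were adjusted for. No miRNA passed for the interaction under any alternative. Of the lists, 0 passed camera under every alternative with an estimated correlation, 1 passed with a preset correlation of 0.01 and 11 passed fry, which does not compare a list with other miRNAs. Apart from these constructions the cause was not tested. Leaving out each array gave 106 to 128 strain calls, 69 to 114 in females, 33 to 51 in males, 0 to 10 for sex and 0 for the interaction and the lists. The difference in brightness ranged from 79.2 to 109.0, that in detected miRNAs from 0.661 to 6.23, and that in the percent of signal of the 10 brightest miRNAs from -0.63 to -0.27. Brightness passed the threshold without NHR female 3 (109.0) and without NHR male 2 (108.2), and the 10 brightest without NHR female 3. Of 64 named miRNAs called for strain, 60 kept call and direction with every array left out, and 3 did so under every other alternative (miR-34a, miR-378 and miR-466b). Under at least 1 alternative, 55 lost the call while keeping the sign, and 41, partly the same miRNAs, changed sign. Low signal limits the rest, since 417 of 677 miRNAs were detected on no array.

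The replicate numbers in the labels were not taken to pair the animals, which are separate, although each number is also 1 slide and 1 row on it in every group. The 24 correlations between the deviations of same-numbered arrays of different groups ran from -0.22 to 0.53, with 16 above 0.1 (among them all 4 of HHR males with NHR females, a pair of groups not compared), and 4 of 16 arrays correlated best with their own number. With the replicate number as a block 124 miRNAs were called for strain, 96 in females, 44 in males, 1 for sex and 0 for the interaction, and no list.

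The scalings moved the median of all tested miRNAs, from -0.106 to 0.23 without scaling, 0.17 with a percentile over all probes, 0.13 with spike-in scaling, 0.068 with median centring, 0.065 in the authors' table, 0.030 with quantile normalization and -0.20 with normexp. Of the 127 called differences 63 changed sign under at least 1 of the 6 scalings. Without scaling, the sign turned for miR-499 to 0.060, miR-133b to 0.19, miR-208b-3p to 0.17, let-7d to 0.21, let-7i to 0.21, let-7a to 0.22, miR-497 to 0.0047, miR-16 to 0.23, miR-15b to 0.24, miR-29c to 0.19, miR-30c to 0.19, miR-30e to 0.21, miR-30a to 0.22, miR-30d to 0.22, miR-23b to 0.20, miR-23a to 0.21, miR-24 to 0.21, miR-27a to 0.21, miR-181d to 0.13, miR-181c to 0.20, miR-181a to 0.20, miR-181b to 0.24, miR-667 to 0.0052, miR-21 to 0.21, miR-26a to 0.25, miR-126 to 0.14, miR-126* to 0.11, miR-143 to 0.21, miR-145 to 0.21, miR-146a to 0.042, miR-7a to 0.054 and miR-421* to 0.15. With a percentile over all probes, the sign turned for miR-499 to 4.6e-04, miR-133b to 0.13, miR-208b-3p to 0.11, let-7d to 0.15, let-7i to 0.15, let-7a to 0.16, miR-16 to 0.17, miR-15b to 0.18, miR-29c to 0.13, miR-30c to 0.13, miR-30e to 0.15, miR-30a to 0.16, miR-30d to 0.16, miR-23b to 0.14, miR-23a to 0.15, miR-24 to 0.15, miR-27a to 0.15, miR-181d to 0.072, miR-181c to 0.14, miR-181a to 0.14, miR-181b to 0.18, miR-21 to 0.15, miR-26a to 0.19, miR-126 to 0.083, miR-126* to 0.049, miR-143 to 0.16, miR-145 to 0.15 and miR-421* to 0.090. In the authors' value table, the sign turned for miR-499 to 0.030, miR-133b to 0.18, miR-208b-3p to 0.042, let-7d to 0.19, let-7i to 0.19, let-7a to 0.20, miR-16 to 0.21, miR-15b to 0.20, miR-29c to 0.077, miR-30c to 0.15, miR-30e to 0.17, miR-30a to 0.18, miR-30d to 0.16, miR-23b to 0.16, miR-23a to 0.16, miR-24 to 0.19, miR-27a to 0.16, miR-181d to 0.032, miR-181c to 0.071, miR-181a to 0.14, miR-181b to 0.12, miR-21 to 0.19, miR-26a to 0.22, miR-126 to 0.13, miR-126* to 0.043, miR-143 to 0.19, miR-145 to 0.054, miR-146a to 0.0056, miR-7a to 0.0040 and miR-421* to 0.020. With spike-in scaling, the sign turned for miR-133b to 0.094, miR-208b-3p to 0.079, let-7d to 0.12, let-7i to 0.12, let-7a to 0.13, miR-16 to 0.14, miR-15b to 0.15, miR-29c to 0.093, miR-30c to 0.094, miR-30e to 0.11, miR-30a to 0.13, miR-30d to 0.13, miR-23b to 0.10, miR-23a to 0.11, miR-24 to 0.11, miR-27a to 0.11, miR-181d to 0.036, miR-181c to 0.10, miR-181a to 0.11, miR-181b to 0.15, miR-21 to 0.12, miR-26a to 0.16, miR-126 to 0.048, miR-126* to 0.014, miR-143 to 0.12, miR-145 to 0.11 and miR-421* to 0.054. With median centring, the sign turned for miR-133b to 0.024, miR-208b-3p to 0.0091, let-7d to 0.045, let-7i to 0.046, let-7a to 0.057, miR-16 to 0.068, miR-15b to 0.077, miR-29c to 0.022, miR-30c to 0.024, miR-30e to 0.044, miR-30a to 0.059, miR-30d to 0.058, miR-23b to 0.034, miR-23a to 0.042, miR-24 to 0.043, miR-27a to 0.041, miR-181c to 0.031, miR-181a to 0.036, miR-181b to 0.079, miR-21 to 0.046, miR-26a to 0.087, miR-143 to 0.050 and miR-145 to 0.041. With a normexp background, the sign turned for miR-31 to -0.15, miR-338 to -0.12, miR-410 to -0.091, miR-218 to -0.017, miR-598-3p to -0.18, miR-341 to -0.19, miR-431 to -0.18, miR-675* to -0.093 and miR-379 to -0.15. With quantile normalization, the sign turned for miR-208b-3p to 0.12, miR-24 to 0.0084, miR-181d to 2.0e-04, miR-181c to 0.012, miR-21 to 0.0071, miR-26a to 0.011, miR-145 to 0.036 and miR-421* to 0.016. With the total gene signal, the sign turned for miR-208b-3p to 0.057.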

Other observations

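All tests in this part were chosen after the results were seen, except the comparison with other miRNAs of chromosome X, the correlation with the brightness slope and the counts of other splits of the arrays. The miRNAs in the next sentences were named after their values were seen. A second cluster on chromosome X lay on the other side of 0 from the miR-532 locus. The 7 tested products of miR-322, miR-503, miR-351, miR-450a and miR-542 had 5 higher members in HHR, led by miR-351 (0.22 ± 0.061 log2, SE, adjusted p = 0.0103) and miR-503 (0.20 ± 0.040, adjusted p = 0.0013), while miR-322 (-0.064 ± 0.030) and miR-450a (0.080 ± 0.039) did not pass limma's threshold. The cluster's median was 0.080 and stayed positive under all 6 scalings, up to 0.42 without scaling, and was -0.039 with normexp, where none was called. The other scalings move most differences upward, so they hardly test this sign. The cluster did not pass camera over 14 clusters (adjusted p = 0.468), nor did the miR-532 locus (adjusted p = 0.114). Both arms of miR-490, encoded within the muscarinic receptor gene Chrm2, were higher, miR-490 by 0.14 ± 0.031 (adjusted p = 0.00236). miR-675*, from the imprinted H19 transcript, was higher, while miR-483 and miR-483*, within Igf2, did not pass (-0.12 ± 0.071 and -0.15 ± 0.13, adjusted p = 0.176 and 0.313).

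Strain differences of miRNAs from the same genomic cluster were closer to each other than those of random clusters. Across 46 clusters with 135 tested miRNAs, neighbours within 10 kb, the permutation p was 0.0052 over 10000 permutations, and it was 0.0091 without the miR-532 locus. Many of these clusters are only the arms of 1 hairpin, and the test was not run without them. It therefore does not show that separate neighbouring miRNAs move together. Across 37 hairpins with both arms tested, the differences of the arms correlated at r = 0.33 (permutation p = 0.0024, across hairpins, which are not independent replicates), short of the 0.5 set for this test.

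The 127 miRNAs called for strain were more than in any of 99 other splits of the arrays within sex (the highest gave 86, so the real split was 1 of 100), which excludes a chance split for the count. The next highest gave 55 and 40. These 3 were the only splits that moved as few as 2 arrays from the real one and so kept most of the strain grouping, while the 96 that moved 4 or more gave at most 1 call. In females 105 calls stood against at most 1 in the other splits (1 of 35 as large), and in males 48 against 0 (1 of 35). For sex, 16 of 100 splits, the real one included, gave as many miRNAs at an unadjusted p under 0.05 as the real 23, with 45 as the highest, and for the interaction 56 of 100, the real one included, gave as many as the real 9, with 45 as the highest, so chance is not excluded for either.

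The lower levels of the 6 miRNAs at the miR-532 locus in HHR were weighed against 3 explanations. Scaling between arrays is argued against, since the median of the 6 was -0.68 and at its highest over the 6 scalings -0.34. A dependence on array brightness is argued against too, since all 6 remained lower with brightness as a covariate. A shift of chromosome X as a whole would lower its other miRNAs, but the 20 others tested had a median of -0.062, with 5 called lower and 5 higher. All 5 higher ones were products of the miR-322 cluster, and outside that cluster the called ones were all lower. The median argues against a shift as large as that of the 6, while a smaller one stays open. A strain difference at this locus may underlie the pattern, as a hypothesis that was not tested. Cross-hybridisation between the 6 stays open without probe sequences. In the authors' table none of the 6 was called (median -0.079). That table compresses levels, but whether this accounts for the lost calls was not tested.

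That most called differences were small and lower in HHR may come from the scaling between arrays, since the share of lower calls fell to 13.5% with a percentile over all probes. The brightness of the arrays stays open as a further source, because the change with brightness within groups correlated only weakly with the strain difference across miRNAs (r = 0.10), below the 0.3 set in advance and above 0. A strain difference in most miRNAs stays open, as untested.

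Within groups, miR-466b, miR-3588 and miR-32*, whose strain differences were wide, shared variation between arrays with miR-206. The median pairwise correlation of the 4 within groups was 0.79 (0.52 to 0.87 for each of the 3 with miR-206). The spread of the 3 within groups was 0.71 to 0.82 against a median of 0.12 over all tested miRNAs. With miR-206 as a covariate their strain differences of -2.13, -2.06 and -1.89 went to -1.85, -1.87 and -1.59 (median -1.85), and all 3 remained called. With brightness as a covariate, all 3 remained called. Because they were detected on at most 2 of the 8 HHR arrays, values near the floor exclude neither the shared variation nor array brightness, and what the shared variation is was not tested. A strain difference stays open as well.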
